A study of Arabidopsis thaliana with 48 samples.

How the data were processed

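The authors grew the line at 21 °C in 16 h light and 8 h dark and drenched the inflorescences with 2 µM dexamethasone (first 8 h after lights on, then each day 4 h after lights on), per the labels. PolyA RNA of 4 biological replicates per day, for day 0 to day 5, was sequenced in 2 batches, per the labels. FastQC, Trim Galore, Salmon 0.12.0 and DESeq2 were used with TAIR10, per the submitters' processing notes. What each of these tools was used for, their settings and the other versions are not given in the sources used here. The deposited table holds expected counts per gene as whole numbers, 1 column per run, which the authors made before deposit. Which of the tools above made them is not given in the sources used here. The hour of sampling and a time course without dexamethasone are not given in the sources used here. The proteome of the same samples is not analysed here.

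The 2 runs of each sample were summed, so that n is 4 per day and 24 samples in all. Over 24 samples the 2 runs of a sample differed little beyond counting error (chi-square per degree of freedom 1.04 to 1.24, median 1.08), against 3.77 to 66.1 (median 15.8) for 36 pairs of replicates of 1 day. Of 23069 genes in the table, 22915 matched the reference gene table, from which symbols were taken. The other 154 were organellar. Coordinates are from the TAIR10.1 annotation. Genes with enough counts (filterByExpr by day, minimum count 10, minimum total 15) were tested, 19747 in all. Genes without a symbol in the table, or with a symbol that it gives to more than 1 gene, appear under their identifiers, except for the fixed list members, which carry the names given to them in the lists.

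The test was the quasi-likelihood F-test of edgeR 4.0.16 on R 4.3.3, with TMM factors and day as the factor over all 24 samples (18 residual degrees of freedom, prior degrees of freedom 4.09). All p were adjusted by Benjamini and Hochberg over all tested genes, with a call at adjusted p under 0.05. The standard error of a log2 fold change is its size over the square root of F. CPM use TMM effective library sizes. Principal components were taken on unscaled log2 CPM (prior count 2) of all tested genes. Tested were the change over the 6 days, each of days 1 to 5 against day 0, and each of the 4 later steps from day to day. The comparisons against day 0 share the day 0 samples, so no overlap between their gene sets is reported.

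Gene lists were tested with camera of limma 3.58.1 on log2 CPM (preset correlation 0.01), with Benjamini and Hochberg adjustment over 22 lists and 9 comparisons, 198 in all. Each was repeated with an estimated correlation between genes and with fry. The 22 lists were floral organ identity and patterning, floral transition and inflorescence identity, meristem and organ boundary, organ polarity, carpel and ovule, anther and tapetum, meiosis, mature pollen, cell division, DNA replication, growth-regulating factors with CIN-type TCPs, gibberellin, cytokinin, auxin and organ initiation, jasmonate, flavonoid, epidermis and cuticle, trichome, photosynthesis, vasculature, circadian clock, and handling and heat stress. They hold 337 genes, 7 of which are absent from the table. Genes of the handling and heat stress list are called handling markers below, after the list name. Handling as the source of their changes was not tested. Counts of list members use the adjustment over all genes, and counts adjusted over the list alone are given beside some of them.

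The groups, the test, the lists, the alternatives and the rule for naming genes were chosen before the data were examined, except those named here and in the closing parts as chosen afterwards. The rule names a fixed core of 24 floral genes in every comparison. It adds the 8 largest rises and 8 largest falls at day 1 and day 5 against day 0 and in each later step. These need adjusted p under 0.05, a mean of at least 5 CPM, groups that do not overlap and a symbol. Where the largest rises or falls are named below, they are the largest among genes that meet this rule. It also names up to 4 members per list with the smallest adjusted p, and members that move against their list. Not every gene that the rule selects is described. CAL was added to the core as a 25th gene since it is mutated in the line. Near copies (AOC1 and AOC2, UGT73B4 and UGT73B5, NIT2, COR15A and COR15B, LHCB1 and RBCS genes) can share reads.

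Alternatives run were DESeq2 1.42.0, size factors of the DESeq2 kind, library totals, no filter, a mean of at least 10 CPM, the replicate number as a block, each replicate and each library left out in turn, each batch alone, batch as a covariate on the runs, the 2 compared days alone, and a fold threshold of 1.5 (glmTreat). In simulated counts with known changes, the test recovered 61.2% of 1.5-fold changes at the lowest (day 4 against day 3, and day 5 against day 4) and 68.7% at the highest (day 2 against day 0). It recovered 85.1% to 88.1% of 2-fold changes over the 9 comparisons. Of its calls there, 2.4% to 7.7% were false, but 13.8% for day 5 against day 0 (27 of 195 calls). Each comparison had a single simulation, with counts drawn independently for each gene. Only 67, 67 and 66 genes were changed, by 1.5-, 2- and 4-fold. Many more genes were called in the real data, so these shares need not hold there.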

Results

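The series sampled inflorescences of an Arabidopsis ap1 cal line that carries AP1 fused to a glucocorticoid receptor domain, on the day of induction and on each of the 5 days after it. Each of the 6 days has 4 biological replicates (n = 4), and each of the 24 samples was sequenced in 2 batches. Summed over the batches, the samples held 26.56 to 27.98 M counts over 23069 genes, and 21672 to 22156 genes were detected per sample. Batch 1 runs held 4.50 to 10.84 M counts and batch 2 runs 16.74 to 22.61 M counts. Values are CPM (counts scaled to the effective library size), mean ± SD with n = 4 per day, and changes are log2 fold changes with their standard error (SE). On a principal component analysis of the 19747 tested genes, component 1 held 46.2% of the variance, component 2 held 13.6% and component 3 held 8.3%. Day 5 replicate 1 lay at 51.65 on component 3, and the other samples of day 5 lay at -24.33 to 1.91.

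**Figure D1:**
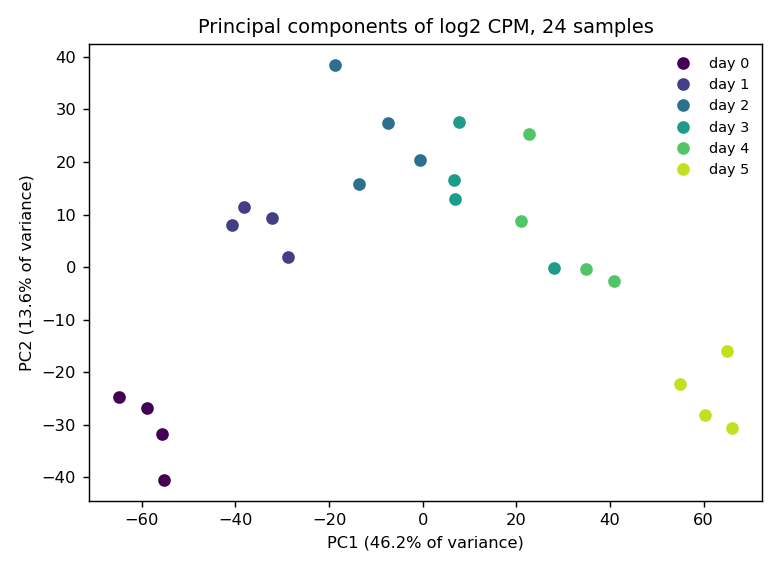
Each point is 1 of 24 samples placed by the principal components of log2 CPM, coloured by day after induction, with component 1 on the horizontal axis and component 2 on the vertical axis (4 samples per day). Days 0 and 5 lie at the 2 ends of component 1, which holds 46.2% of the variance.

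The series asks how transcripts change while AP1 activity starts flower development, and its protein part is not analysed here. AP3 (AT3G54340, chromosome 3, 20119140 to 20121314), a petal and stamen identity gene, rose from 8.74 ± 2.4 CPM at day 0 to 68.4 ± 5.2 at day 1 and 179 ± 6.1 at day 5 (n = 4). AG (AT4G18960, chromosome 4, 10382856 to 10388539), needed for stamens and carpels, rose from 3.20 ± 0.87 to 11.7 ± 2.8 and then 33.4 ± 2.3 CPM over the same days. LFY (AT5G61850, chromosome 5, 24844248 to 24846989), a floral meristem identity gene, had its highest mean at day 2, 114 ± 6.8 CPM, between 48.5 ± 3.4 at day 0 and 62.0 ± 9.7 at day 5. SVP (AT2G22540, chromosome 2, 9579647 to 9583901), a repressor of flowering and of early floral organ genes, fell at every step from 101 ± 7.5 to 17.8 ± 1.8 CPM. AP1 itself (AT1G69120, chromosome 1, 25982294 to 25986349) rose from 184 ± 20 to 296 ± 34 CPM. Its reads cannot separate the transgene from the mutated gene of the line.

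Among the other floral genes, PI (AT5G20240), the partner of AP3, went from 61.0 ± 6.8 CPM at day 0 to 152 ± 12 at day 5. The E-class genes SEP1 (AT5G15800), SEP2 (AT3G02310) and SEP3 (AT1G24260, chromosome 1, 8593536 to 8596123) went from 20.3 ± 3.6 to 64.2 ± 1.6, from 34.9 ± 4.2 to 212 ± 5.9 and from 14.4 ± 3.0 to 114 ± 2.3 CPM. The carpel gene CRC (AT1G69180) went from 3.89 ± 1.1 to 40.6 ± 4.3 CPM, with most of the gain after day 2 (7.58 ± 4.0). SUP (AT3G23130), which bounds the stamen whorl, was highest at day 3 (2.96 ± 0.98 CPM against 0.181 ± 0.073 at day 0). The sporocyte gene SPL/NZZ (AT4G27330) went from 0.123 ± 0.082 to 2.46 ± 0.67 CPM. UFO (AT1G30950), a cofactor of LFY, went from 29.9 ± 5.4 to 18.4 ± 0.58 CPM. DYT1 (AT4G21330), an early tapetum regulator, was too low to test, with 13 summed counts at its highest day.

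TFL1 (AT5G03840), which keeps the inflorescence indeterminate, fell from 29.5 ± 2.6 to 15.3 ± 0.92 CPM by day 1 and 11.9 ± 2.3 by day 5. The flowering time genes SOC1 (AT2G45660), AGL24 (AT4G24540), FD (AT4G35900) and FUL (AT5G60910) went from 185 ± 29 to 77.8 ± 8.9, from 94.4 ± 8.1 to 26.9 ± 2.0, from 154 ± 9.0 to 37.0 ± 2.4 and from 155 ± 9.3 to 110 ± 11 CPM. SPL9 (AT2G42200), a phase change regulator, was lowest at day 2, 85.1 ± 9.8 CPM against 138 ± 8.1 at day 0 and 127 ± 28 at day 5. The stem cell genes WUS (AT2G17950), CLV3 (AT2G27250) and STM (AT1G62360) went from 5.62 ± 1.1 to 1.80 ± 0.23, from 1.24 ± 0.21 to 0.142 ± 0.084 and from 159 ± 7.1 to 69.3 ± 11 CPM. DMC1 (AT3G22880), a meiotic recombinase, was lowest at day 3 (8.94 ± 1.1 CPM against 17.5 ± 1.3 at day 0). CAL (AT1G26310), mutated in the line, went from 18.5 ± 2.4 to 6.09 ± 0.68 CPM.

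In the test over the 6 days 9661 of 19747 genes changed (48.9%, edgeR, adjusted p under 0.05). All 24 core genes that could be tested were among them, from SVP (adjusted p = 1.18e-15) and AP3 (adjusted p = 4.58e-15) to SPL9 (adjusted p = 0.000532). Of the changed genes 37.9% had their highest mean at day 5 and 32.2% at day 0, against 3.9% at day 3.

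**Figure D2:**
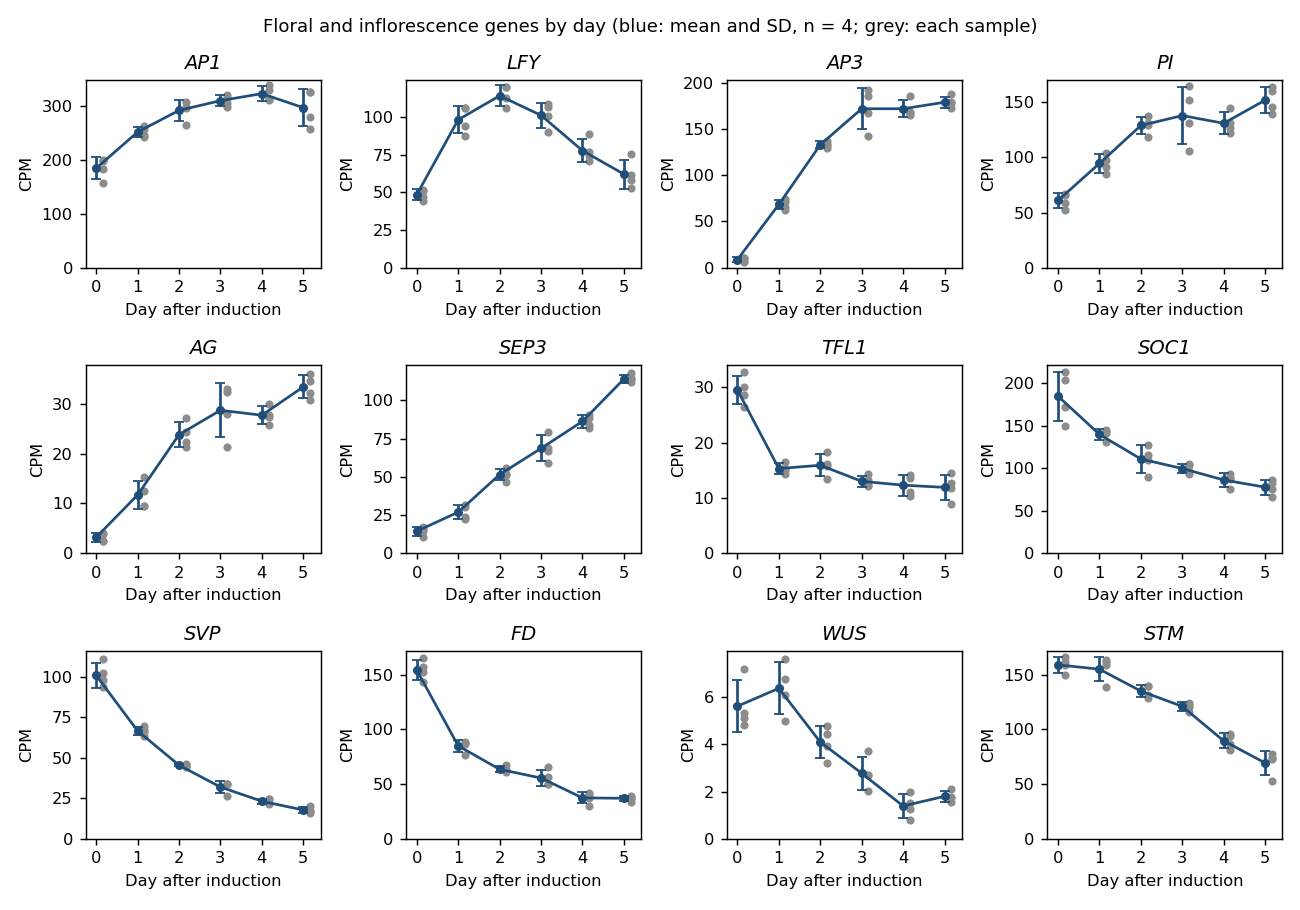
CPM on the vertical axis against day after induction for 12 core genes, grey points for each sample and blue points with bars for mean ± SD (n = 4 per day). AP3 goes from 8.74 ± 2.4 to 179 ± 6.1 CPM while SVP goes from 101 ± 7.5 to 17.8 ± 1.8 CPM.

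By day 1 the floral organ genes were already up against day 0 (n = 4 per day). AP3 rose by 2.97 (SE 0.13), AG by 1.87 (SE 0.18) and LFY by 1.02 (SE 0.10), with adjusted p = 1.53e-12, 5.76e-07 and 4.92e-07. JAG (AT1G68480), which promotes outgrowth of floral organs, rose from 0.628 ± 0.16 to 4.34 ± 0.56 CPM, and AP2 (AT4G36920), a sepal and petal identity gene, from 34.7 ± 2.7 to 67.0 ± 3.2. PI (log2 change 0.63), SEP1 (0.57), SEP2 (0.90), SEP3 (0.90), SUP (1.59) and AP1 (0.45) rose as well. FOP1 (AT5G53390), a wax synthase gene named for folded petals, rose from 0.409 ± 0.10 to 3.48 ± 0.32 CPM. In the floral organ identity and patterning list 14 of 23 genes rose, also 14 adjusted over the list alone (camera, adjusted p = 1.25e-14, and 0.0179 with an estimated correlation).

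Falling by day 1 were FD (log2 change -0.86), SVP (-0.60), TFL1 (-0.95), AGL24 (-0.49) and SPL15 (AT3G57920), a phase change factor that went from 44.8 ± 1.5 to 27.3 ± 1.2 CPM. The floral transition and inflorescence identity list fell with 8 of 20 genes, 11 adjusted over the list alone (camera, adjusted p = 1.13e-06, and adjusted p = 0.0604 with an estimated correlation). Of the auxin and organ initiation list 5 of 12 genes rose (camera, adjusted p = 0.00489, and adjusted p = 0.146 with an estimated correlation), among them the auxin synthesis gene YUC1 (AT4G32540, 3.44 ± 0.35 to 5.95 ± 0.31 CPM) and ANT (206 ± 21 to 273 ± 14). CUC1, an organ boundary gene, rose from 19.2 ± 1.3 to 29.2 ± 1.7 CPM in a meristem and organ boundary list that was not called (3 of 15 rose, adjusted p = 0.53). The ovule gene INO (AT1G23420) fell from 4.18 ± 0.42 to 1.62 ± 0.12 CPM and YAB2 from 15.9 ± 1.8 to 10.7 ± 1.8, while PHB rose by 0.36. The organ polarity list was not called (3 rises and 2 falls of 15, adjusted p = 0.245).

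Among the 8 largest rises at day 1, AOX1A (AT3G22370), the alternative oxidase, rose from 10.5 ± 4.5 to 108 ± 21 CPM (log2 change 3.36, SE 0.35, adjusted p = 2.34e-06). NDB4 (AT2G20800), a mitochondrial NADH dehydrogenase, rose from 0.257 ± 0.11 to 7.73 ± 3.4 CPM, and ERF71 (AT2G47520), a low-oxygen response factor, from 0.948 ± 0.89 to 22.8 ± 3.4. The efflux gene DTX1 (AT2G04040) rose from 0.526 ± 0.23 to 5.02 ± 1.3 CPM and the glycosyltransferase gene UGT73B4 (AT2G15490) from 0.182 ± 0.19 to 2.04 ± 0.41. Reads of UGT73B4 may come in part from its near copy UGT73B5. ZAT12, of the handling and heat stress list, rose from 2.65 ± 0.28 to 5.86 ± 1.0 CPM, and that list was not called (1 of 8 rose, camera, adjusted p = 0.0995).

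Of the 8 largest falls at day 1, 4 kept their calls without any single library: MIOX4 (AT4G26260), an inositol oxygenase gene (28.8 ± 10 to 4.75 ± 2.4 CPM), the cold-regulated genes COR27 (AT5G42900, 155 ± 30 to 56.8 ± 14) and COR15B (AT2G42530, 21.9 ± 3.1 to 8.33 ± 1.3), and the xylosidase gene BXL1 (AT5G49360, 22.7 ± 8.7 to 8.71 ± 3.0). In the photosynthesis list 19 of 24 genes fell, 21 adjusted over the list alone (camera, adjusted p = 3.93e-11, and adjusted p = 0.355 with an estimated correlation), with GAPA going from 747 ± 150 to 528 ± 50 CPM. Of the clock list 4 of 17 genes fell, the evening genes ELF4 (50.7 ± 3.3 to 22.3 ± 2.3 CPM) and LUX (54.5 ± 3.8 to 40.3 ± 4.9) with the smallest adjusted p. The list, which mixes morning and evening genes, was not called (camera, adjusted p = 0.96). Adjusted over the list alone it held 4 rises and 4 falls, and such opposite changes cancel in camera's test of a shared direction. In a separate set of evening genes, chosen after the clock list was seen and measured in the same samples, the median log2 change was -0.65. Of its 5 genes 2 fell, COR28 (-1.15) and BOA (-0.76), and all 5 adjusted over the list alone. In its morning counterpart 2 of 13 rose and the median was 0.21. TCP4, a CIN-type TCP gene, fell by 0.75 and TCP3 by 0.68, against a rise of 0.43 in GRF2.

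At day 1, 831 genes rose and 1155 fell against day 0 (edgeR, adjusted p under 0.05), 206 and 131 of them by at least 2-fold. With library totals in place of TMM 64.9% of the calls were rises, against 41.8%. Leaving out day 0 replicate 2 gave 464 rises and 615 falls, day 1 replicate 1 gave 474 and 742, day 1 replicate 2 gave 442 and 708, and day 1 replicate 4 gave 503 rises. The calls of SOC1 (log2 change -0.40) ended without day 0 replicate 1 or replicate 4 (highest adjusted p = 0.0668), of SPL9 (-0.49) without day 0 replicate 2 (0.0535), and of DMC1 (-0.38) without any of 5 libraries of the 2 days (0.0998). Those of MIOX2 (72.7 ± 16 to 16.9 ± 7.6 CPM), ERD5, GDPD2 and DIN10 ended without any of 5 to 11 single libraries, with highest adjusted p = 0.0898, 0.116, 0.117 and 0.13. The anther and tapetum list was called at day 1 (2 rises and 1 fall of 21, camera, adjusted p = 0.0128) but not with an estimated correlation (adjusted p = 0.774), with fry (0.173), with library totals (0.0932) or without replicate 3 (0.18).

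Against day 0, the petal gene RBE (AT5G06070) rose by day 2 from 0.0572 ± 0.023 to 2.39 ± 0.29 CPM (n = 4, log2 change 5.28, SE 0.30, adjusted p = 3.04e-11). AP3 stood 3.93 (SE 0.13) above day 0 at day 2, JAG 3.68 and AG 2.89. Of the floral organ identity and patterning list 14 of 23 genes rose and 2 fell, 16 and 2 adjusted over the list alone (camera, adjusted p = 6.36e-14, and 0.0179 with an estimated correlation). SVP fell by 1.16, FD by 1.28 and AGL24 by 0.89, within 11 of 20 falls in the floral transition list (camera, adjusted p = 7.62e-07, and adjusted p = 0.0604 with an estimated correlation). FIL (AT2G45190), an organ polarity gene, rose from 97.0 ± 4.4 to 199 ± 29 CPM and YAB3 from 41.3 ± 5.4 to 62.2 ± 5.4, while INO fell to 0.704 ± 0.052. The polarity list was up (8 rises and 1 fall of 15, camera, adjusted p = 0.0177), which ended with an estimated correlation (adjusted p = 0.344) and without replicate 3 (0.0726) or 4 (0.0523).

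At day 2 the cytokinin activation gene LOG3 rose from 0.604 ± 0.25 to 4.42 ± 0.67 CPM, while LOG7 fell from 12.1 ± 1.1 to 6.67 ± 0.70. The gibberellin catabolism gene GA2ox1 rose from 0.0761 ± 0.0022 to 2.18 ± 0.59 CPM, and the DELLA gene RGL2 from 5.00 ± 1.1 to 13.1 ± 1.7. The photosynthesis list fell with 22 of 24 genes (camera, adjusted p = 4.17e-13, and adjusted p = 0.29 with an estimated correlation). On the same day the handling and heat stress list rose with 4 of 8 genes, 6 adjusted over the list alone (camera, adjusted p = 0.000643, and adjusted p = 0.156 with an estimated correlation), led by ZAT12 (17.1 ± 4.7 CPM) and WRKY40 (18.8 ± 5.1 against 3.80 ± 1.4). The anther and tapetum list was called with 3 rises and 1 fall of 21 (camera, adjusted p = 0.0139), which ended with an estimated correlation (adjusted p = 0.774) and with fry (0.0917). EMS1, a receptor needed for tapetum fate, rose from 38.9 ± 4.1 to 54.9 ± 3.7 CPM, while TPD1, its ligand, fell from 9.12 ± 1.0 to 5.68 ± 0.39. SPL/NZZ (0.636 ± 0.55 CPM) lost its call without day 2 replicate 4 or any of day 0 replicates 1 to 3 (highest adjusted p = 0.237). In this comparison 2233 genes rose and 2439 fell (edgeR, adjusted p under 0.05), and no single library moved either count by more than 1.5 times.

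By day 3, FIL stood at 293 ± 34 CPM and YAB3 at 84.8 ± 5.1 (n = 4), 1.60 and 1.04 above day 0. PHV, which sets the upper side of organs, rose from 108 ± 14 to 175 ± 9.9 CPM. The polarity list held 9 rises and 2 falls among 15 genes (camera, adjusted p = 0.00144, and adjusted p = 0.184 with an estimated correlation). In the floral organ identity list 16 of 23 genes rose and 3 fell (camera, adjusted p = 2.26e-12, and 0.0183 with an estimated correlation). In the floral transition list 12 of 20 fell and 1 rose (camera, adjusted p = 9.10e-07, and adjusted p = 0.0604 with an estimated correlation), and SVP stood at 32.0 ± 3.7 CPM. The jasmonate signalling genes JAZ10 (log2 change 1.56, to 51.3 ± 13 CPM) and JAZ1 (16.5 ± 7.5 to 43.7 ± 11) and the synthesis gene LOX3 (8.48 ± 3.1 to 19.9 ± 3.5) rose. The jasmonate list held 8 rises of 11 (camera, adjusted p = 0.00488, and adjusted p = 0.566 with an estimated correlation).

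At day 3, 22 of 24 photosynthesis genes fell against day 0 (camera, adjusted p = 3.67e-13, and adjusted p = 0.286 with an estimated correlation). RBCS2B went from 408 ± 130 to 89.9 ± 41 CPM, though RBCS copies share reads. Handling markers stayed up, 5 of 8 (camera, adjusted p = 0.00211, and adjusted p = 0.184 with an estimated correlation), ZAT12 at 17.9 ± 3.0 CPM. The anther and tapetum list was called up (9 rises and 1 fall of 21, 15 and 1 adjusted over the list alone, camera, adjusted p = 0.0462). That call ended with an estimated correlation (adjusted p = 0.848), with fry (0.0898), with library totals (0.0932) and without replicate 1 (0.091) or 4 (0.268). The test called 2882 rises and 2861 falls (edgeR, adjusted p under 0.05), and no single library moved them by more than 1.5 times.

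At day 4 against day 0 the meristem genes had fallen: BLH8 from 53.9 ± 0.90 to 22.5 ± 1.6 CPM, BLH9 from 130 ± 8.1 to 85.6 ± 3.3, STM to 89.5 ± 6.8 and WUS to 1.39 ± 0.50 (n = 4). Of the meristem and organ boundary list 10 of 15 genes fell and 1 rose (camera, adjusted p = 4.20e-05, and adjusted p = 0.184 with an estimated correlation). At day 2 this list had 4 rises and 4 falls (adjusted p = 0.73) and at day 3 it had 3 and 8 (adjusted p = 0.133). Genes of the epidermis and cuticle rose, PDF1 from 1300 ± 70 to 2210 ± 51 CPM, the wax regulator SHN1 (AT1G15360) from 0.869 ± 0.25 to 9.35 ± 2.6 and the acyl-CoA synthetase gene LACS2 from 88.4 ± 6.6 to 176 ± 9.3. That list had 10 rises among 15 genes (camera, adjusted p = 9.72e-05, and adjusted p = 0.409 with an estimated correlation). GRF8, a growth-regulating factor gene, rose from 7.90 ± 0.69 to 39.4 ± 3.3 CPM and TCP10 from 25.3 ± 2.9 to 70.1 ± 2.6, while GRF6 fell by 0.93.

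At day 4, organ identity genes held 17 rises and 3 falls of 23 (camera, adjusted p = 3.93e-11, and 0.0224 with an estimated correlation) and transition genes 1 rise and 13 falls of 20 (adjusted p = 6.81e-06, and adjusted p = 0.0834 with an estimated correlation). FD stood at 37.4 ± 5.1 CPM. Polarity genes held 10 rises and 2 falls of 15 (adjusted p = 0.00379, and adjusted p = 0.23 with an estimated correlation) and jasmonate genes 8 rises of 11 (adjusted p = 0.00407, and adjusted p = 0.558 with an estimated correlation). Photosynthesis genes held 21 falls of 24 (adjusted p = 9.03e-10, and adjusted p = 0.42 with an estimated correlation) beside 3 rises of 8 handling markers (adjusted p = 0.00747, and adjusted p = 0.248 with an estimated correlation). FUL (130 ± 8.5 CPM) lost its call without day 0 replicate 2 or day 4 replicate 2 (highest adjusted p = 0.0511). In total 3509 genes rose and 3466 fell (edgeR, adjusted p under 0.05), and no single library moved these counts by more than 1.5 times.

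Between day 0 and day 5, RAP2.6 (AT1G43160), a stress response factor, rose from 0.278 ± 0.22 to 56.7 ± 14 CPM (n = 4, log2 change 7.66, SE 0.78, adjusted p = 5.32e-08). The jasmonate synthesis genes AOC1 (AT3G25760) and AOC2 (AT3G25770) rose to 24.8 ± 11 and 79.3 ± 15 CPM from 0.134 ± 0.070 and 0.628 ± 0.38, and these near copies may share reads. NIT2 (AT3G44300), a nitrilase gene with near copies, rose from 0.221 ± 0.12 to 36.1 ± 16 CPM, CYP79B3 (AT2G22330), of indole glucosinolate synthesis, from 0.360 ± 0.062 to 42.2 ± 25, and ERF53 (AT2G20880) from 0.199 ± 0.032 to 16.5 ± 5.1. UGT73B4 reached 27.0 ± 14 CPM and AT2G24210 reached 21.9 ± 7.3. All 11 jasmonate genes rose (camera, adjusted p = 8.28e-07, and adjusted p = 0.199 with an estimated correlation), LOX3 to 97.6 ± 31 CPM and JAZ10 to 140 ± 21. All 8 handling markers rose too (camera, adjusted p = 0.000359, and adjusted p = 0.139 with an estimated correlation), WRKY40 to 45.0 ± 30 CPM.

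Among genes that met the naming rule, with a mean of at least 5 CPM, the largest falls by day 5 were in LSH1 (AT5G28490), a boundary-type ALOG gene (52.9 ± 2.9 to 4.07 ± 0.21 CPM), and LBD19 (AT2G45410, 25.0 ± 2.6 to 2.75 ± 0.70). TEL2 (AT1G67770, 22.7 ± 0.58 to 3.84 ± 0.94) and the cytokinin inhibitor AHP6 (AT1G80100, 20.6 ± 1.7 to 3.66 ± 1.5) were also among the 8 largest. SAP (AT5G35770), a regulator of flower and ovule growth, fell from 21.0 ± 1.9 to 4.08 ± 0.83 CPM and JMJD5 (AT3G20810), a clock-linked demethylase gene, from 125 ± 47 to 24.7 ± 12. SVP (-2.51) and RBCS2B (-2.33) complete the 8 largest under that rule, which leaves out genes of lower mean such as CLV3. STM fell by 1.20, CLV3 fell by 3.09 and BLH8 fell by 1.62, within 13 falls and 1 rise of 15 meristem and boundary genes (camera, adjusted p = 5.56e-07, and adjusted p = 0.0936 with an estimated correlation). The transition list had 11 falls and 5 rises of 20 (camera, adjusted p = 0.000573, and adjusted p = 0.184 with an estimated correlation).

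Organ genes at day 5 were mixed in more lists. AP3 stood 4.36 above day 0, SEP3 2.99, SEP2 2.60 and AP2 2.01, while UFO fell by 0.70 against its list (17 rises and 5 falls of 23, camera, adjusted p = 7.95e-08, and adjusted p = 0.0604 with an estimated correlation). FIL stood at 267 ± 20 CPM, while ETT, an auxin response factor gene of the lower organ side, fell from 323 ± 16 to 161 ± 6.7. The polarity list was no longer called (8 rises and 3 falls of 15, adjusted p = 0.104). In the carpel and ovule list NGA1 rose from 3.42 ± 0.73 to 19.1 ± 1.5 CPM and NGA2 from 3.13 ± 0.69 to 11.8 ± 1.1. STY1 (13.2 ± 0.67 to 5.19 ± 0.64) and INO (to 0.122 ± 0.088) fell there, and the list was not called (8 rises and 4 falls of 13, adjusted p = 0.144). SHN1 reached 39.1 ± 15 CPM with 13 of 15 cuticle genes up (camera, adjusted p = 6.71e-08, and adjusted p = 0.196 with an estimated correlation). TT7, of flavonoid synthesis, rose from 15 ± 2.9 to 74.3 ± 26 CPM, with 6 of 10 rises in its list (camera, adjusted p = 0.0231), a call lost with an estimated correlation (adjusted p = 0.801) and without replicate 3 (0.0503). The photosynthesis list held 22 falls of 24 (camera, adjusted p = 8.79e-08, and adjusted p = 0.524 with an estimated correlation).

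In the gibberellin list at day 5, RGL2 rose by 2.55, GID1B by 1.66 and the catabolism gene GA2ox6 from 0.191 ± 0.12 to 8.39 ± 1.9 CPM (6 rises and 4 falls of 15, adjusted p = 0.514). LOG3 rose by 3.44 and the cytokinin oxidase gene CKX1 by 3.05, against -1.89 for LOG7 (4 rises and 6 falls of 15 cytokinin genes, adjusted p = 0.431). GRF8 rose by 2.47 and TCP13 by 1.83, while GIF1, a growth coactivator, fell by 0.67 (11 rises and 5 falls of 18, adjusted p = 0.078). The trichome inhibitor TRY rose by 3.29 while the trichome and epidermal factor GL2 fell by 1.39 (2 rises and 4 falls of 9, adjusted p = 0.625). The sieve element gene SEOR1 rose by 0.51 while the xylem genes IRX3 and XCP2 fell by 0.73 and 0.79 (2 rises and 6 falls of 9, adjusted p = 0.137). CYCB1;1 fell by 0.34 and CYCB1;3 by 0.48, with CYCB2;1 up by 0.55 (1 rise and 8 falls of 15 cell division genes, adjusted p = 0.116). EMS1 rose by 0.88, while ROXY1, an anther glutaredoxin gene, fell by 0.91 and BAM1 by 0.63 (8 rises and 3 falls of 21, adjusted p = 0.149). TOC1 fell by 0.62 and ELF4 by 1.36 in a clock list with 5 rises and 5 falls of 17 (adjusted p = 0.84), and AGP6, the only mature pollen gene tested, was at 0.406 ± 0.071 CPM (adjusted p = 0.868). ASY1, of the meiotic chromosome axis, fell by 1.79 and DMC1 by 0.59 in a meiosis list that was not called (5 falls of 16, adjusted p = 0.153).

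In all 4791 genes rose and 4521 fell at day 5 against day 0 (edgeR, adjusted p under 0.05), 1872 and 612 of them by at least 2-fold. All 16 genes with the largest changes and all 23 called core genes kept their calls without any single library.

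**Figure D3:**
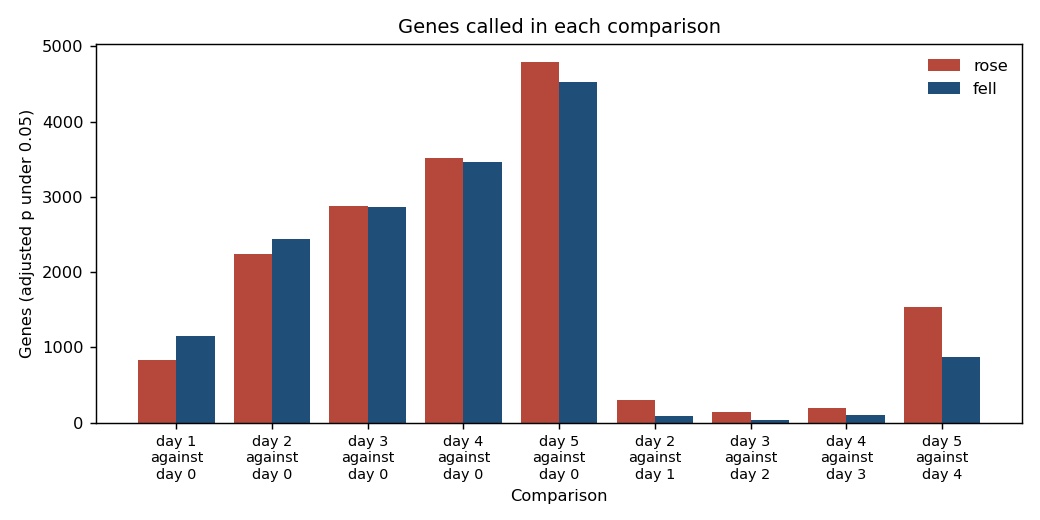
Bars give the number of genes that rose (red) and fell (blue) at adjusted p under 0.05 in each of the 9 comparisons (edgeR, n = 4 per day). Among the 4 steps after day 1, day 5 against day 4 has the most calls, with 1531 rises and 872 falls.

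From day 1 to day 2 floral organ genes went on rising (n = 4 per day). RBE rose from 0.570 ± 0.16 to 2.39 ± 0.29 CPM (log2 change 2.05, SE 0.21, adjusted p = 3.27e-06), AP3 by 0.96 (SE 0.12), AG by 1.02 and SUP by 1.86. SEP3 rose by 0.94 and SEP2 by 0.70, and 10 of 23 organ identity genes rose, 13 adjusted over the list alone (camera, adjusted p = 5.60e-12, and 0.0183 with an estimated correlation). FOP1 rose from 3.48 ± 0.32 to 12.0 ± 2.1 CPM, YAB3 from 34.8 ± 2.2 to 62.2 ± 5.4, FIL from 120 ± 2.8 to 199 ± 29 and YUC1 from 5.95 ± 0.31 to 10 ± 1.2. The polarity list was up with 3 rises and 1 fall of 15, 6 and 3 adjusted over the list alone (camera, adjusted p = 0.0168), but not with an estimated correlation (adjusted p = 0.344) or without replicate 3 (0.157) or 4 (0.0523). NGA1, a style growth gene, rose by 0.99, LOG3 by 1.45 and the receptor gene GID1B by 0.80.

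SVP fell from 66.7 ± 2.5 to 45.5 ± 0.73 CPM and AGL24 by 0.40 in the same step. The transition list held 1 rise and 3 falls of 20, 2 and 5 adjusted over the list alone (camera, adjusted p = 0.000643, and adjusted p = 0.184 with an estimated correlation). LBD19 (15.2 ± 1.2 to 9.08 ± 0.33 CPM), LSH1 (23 ± 2.0 to 14.3 ± 1.3), STY1, a style gene (12.7 ± 1.1 to 8.60 ± 0.72), NADP-ME3 (AT5G25880, 18.9 ± 1.4 to 11.2 ± 2.1), TRM24 (AT5G51850) and AT2G33880 were among the largest falls. BLH8 fell by 0.40. UGT73B4 (2.04 ± 0.41 to 13.2 ± 9.4 CPM), the protein kinase gene AGC2-1 (AT3G25250, 3.26 ± 0.37 to 11.8 ± 4.1) and the cytochrome P450 gene CYP81D8 (AT4G37370, 13.7 ± 2.6 to 49.1 ± 19) were among the largest rises. Handling markers moved with them, ZAT12 from 5.86 ± 1.0 to 17.1 ± 4.7 CPM and 3 of 8 genes, 5 adjusted over the list alone (camera, adjusted p = 4.32e-05, and adjusted p = 0.0834 with an estimated correlation).

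The photosynthesis list was lower at day 2 than at day 1 as a group (camera, adjusted p = 6.81e-06), lost with an estimated correlation (adjusted p = 0.652) and with fry (0.217). LHCB1.1 was at 407 ± 80 against 586 ± 59 CPM. PDF1 rose from 1250 ± 42 to 1620 ± 150 CPM. Of the cuticle list 2 of 15 genes rose (camera, adjusted p = 0.0252), lost with an estimated correlation (adjusted p = 0.775), with fry (0.318) and without replicate 1 (0.128) or 3 (0.204). The meiosis list was down (camera, adjusted p = 0.00598), lost with an estimated correlation (adjusted p = 0.237) and without replicate 1 (0.0624). DMC1, its only fall among 16, went from 13.5 ± 0.46 to 9.52 ± 1.2 CPM and lost its call without day 1 replicate 1 or 3 or day 2 replicate 2 (highest adjusted p = 0.0713).

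This step held 294 rises and 82 falls (edgeR, adjusted p under 0.05), and 27 genes rose beyond a fold of 1.5 (glmTreat). With library totals 66.7% of its calls were rises, against 78.2%. Rises went to 158, 155 and 189 without day 1 replicates 1, 2 and 4, to 170 without day 2 replicate 1 and to 492 without day 5 replicate 1. Falls went to 23, 26, 44 and 34 without day 1 replicates 1 to 4, to 44, 42 and 35 without day 2 replicates 1, 2 and 4, and to 137 without day 5 replicate 1. FD (-0.42) lost its call without day 1 replicate 1 or 2 or day 2 replicate 1 (highest adjusted p = 0.0666). PI (0.45), SEP1 (0.38), UGT74E2, PHT3;2, DTX1, UGT73B5 and AT1G10710 lost theirs without any of 5 or 6 libraries, with adjusted p up to 0.191, and TEM1 (0.78), a flowering repressor that rose against its list, without any of 14 (0.148).

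Day 3 differed from day 2 in few genes (n = 4 per day). ARD3 (AT2G26400), of the methionine cycle, rose from 4.80 ± 0.79 to 10.7 ± 0.44 CPM (log2 change 1.15, SE 0.13, adjusted p = 0.000102). CORI3 (AT4G23600), a jasmonate-induced lyase gene, rose from 19.6 ± 7.2 to 82.6 ± 46 CPM and ERF53 from 1.49 ± 0.90 to 5.93 ± 2.1. AGO5 (AT2G27880), an argonaute of germline cells, fell from 37.1 ± 3.5 to 22.0 ± 1.2 CPM (log2 change -0.76, adjusted p = 0.0011), LSH1 from 14.3 ± 1.3 to 8.69 ± 1.6, SVP from 45.5 ± 0.73 to 32.0 ± 3.7 and BLH8 from 39.9 ± 1.9 to 28.7 ± 2.5. FIL rose by 0.56, NGA2 by 0.98, CKX1 by 1.73 and TCP10 from 18.7 ± 1.7 to 36.5 ± 11 CPM.

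In the growth-regulating factor and TCP list 4 of 18 genes rose, 5 adjusted over the list alone (camera, adjusted p = 4.42e-05, and adjusted p = 0.184 with an estimated correlation). The polarity list was up with 4 rises and 1 fall of 15 (camera, adjusted p = 0.00165), lost with an estimated correlation (adjusted p = 0.184) and without replicate 1 (0.0966). Organ identity genes were up, 2 of 23 and 6 adjusted over the list alone (camera, adjusted p = 0.00151, and adjusted p = 0.272 with an estimated correlation). Meristem genes were down, 1 of 15 and 5 adjusted over the list alone (camera, adjusted p = 0.000832), lost with an estimated correlation (adjusted p = 0.262) and without replicate 3 (0.067). The transition list was down, 2 of 20 (camera, adjusted p = 0.0231), lost with an estimated correlation (adjusted p = 0.42), with fry (0.12) and without replicate 2 (0.0791) or 3 (0.0733). Jasmonate (camera, adjusted p = 0.000101), flavonoid (0.000113) and cuticle genes (0.00134) were up as groups, each lost with an estimated correlation (adjusted p = 0.344, 0.484 and 0.542) and with fry (0.0845, 0.137 and 0.167). LOX3 was at 19.9 ± 3.5 against 11.4 ± 2.4 CPM, TT7 at 25.9 ± 12 against 11.4 ± 2.5 and CER1 at 205 ± 61 against 139 ± 25. The photosynthesis call, down (camera, adjusted p = 0.0195), was lost with an estimated correlation (adjusted p = 0.9), with fry (0.65) and without replicate 1 (0.542) or 4 (0.267), and GAPB was at 181 ± 29 against 201 ± 23 CPM.

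In this step 137 genes rose and 35 fell (edgeR, adjusted p under 0.05), with 1 rise beyond a fold of 1.5 (glmTreat). Rises went to 73, 31, 62 and 90 without day 2 replicates 1 to 4, and to 79 and 48 without day 3 replicates 2 and 4. Falls went to 23 without day 0 replicate 1, to 22 and 21 without day 1 replicates 1 and 2, and to 19, 9, 16 and 20 without day 2 replicates 1 to 4. They went to 11 and 12 without day 3 replicates 2 and 4, and to 54 without day 5 replicate 1. AGL24 (-0.34) lost its call without day 3 replicate 4 (adjusted p = 0.0596), Rap2.6L (1.28) without day 2 replicate 2 (0.0523), and GRF8 (0.66), TCP2 (0.53), YAB3 (0.45) and AS2 (0.82) without day 2 replicate 2 or day 3 replicate 4 (up to 0.0966). LBD19 (-0.65) lost its call without day 2 replicate 2 or 3 or day 3 replicate 2 (0.059), EEL without day 2 replicate 2 or 4 or day 3 replicate 4 (0.149), and AT2G24210 without day 2 replicate 1 or 2 or day 3 replicate 4 (0.0674). SEP2, JAG, ILL6, AOC1, PIP2B, AT4G31910 and CHR40 lost theirs without any of 5 to 19 libraries (up to 0.208). Splitting the 8 samples of these 2 days in all 35 ways gave 21 calls for the real split and 44 for another, so chance differences between libraries are not excluded for this step.

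In day 4 against day 3 (n = 4 per day), FPF1 (AT5G24860), a flowering promoting gene, fell from 70.6 ± 5.9 to 43.0 ± 4.2 CPM (log2 change -0.72, SE 0.08, adjusted p = 0.000138). The boundary gene CUC2 fell from 32.4 ± 1.6 to 22.8 ± 1.4 CPM, STM from 121 ± 3.8 to 89.5 ± 6.8, and MNP (AT3G50870), a boundary GATA factor, from 26.4 ± 3.4 to 16.9 ± 0.32. AHP6 fell from 10.7 ± 1.6 to 5.53 ± 0.95 CPM, LSH10 (AT2G42610) from 10.6 ± 0.11 to 5.84 ± 0.82, LSH1 by 0.71, FD by 0.57 and SVP by 0.46. In the meristem and boundary list 8 of 15 genes fell, 11 adjusted over the list alone (camera, adjusted p = 4.17e-13, and 0.0183 with an estimated correlation). The auxin and organ initiation list fell, 3 of 12 (camera, adjusted p = 0.000113, and 0.0498 with an estimated correlation), with AIL6 at 41.7 ± 5.3 against 59.1 ± 8.2 CPM.

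Rising from day 3 to day 4 were NIT2 (2.63 ± 0.76 to 14.5 ± 7.2 CPM), SHN1 (2.01 ± 1.1 to 9.35 ± 2.6) and UGT76E11 (AT3G46670, 3.78 ± 1.2 to 9.04 ± 2.6). GRF8 rose by 0.83, TCP13 by 1.09 and TCP10 by 0.94, while GIF1 fell by 0.29 against its list. The list held 6 rises and 1 fall of 18 (camera, adjusted p = 0.00432) and lost its call with an estimated correlation (adjusted p = 0.355) and without replicate 2 (0.0989) or 3 (0.106). The cuticle list was up, 2 of 15 and 8 adjusted over the list alone (camera, adjusted p = 1.15e-08, and adjusted p = 0.184 with an estimated correlation). The cytokinin list was down by camera with 1 rise and 1 fall of 15, and 1 rise and 9 falls adjusted over the list alone (adjusted p = 8.25e-06, and adjusted p = 0.184 with an estimated correlation). Carpel and ovule genes were up, 2 of 13 (camera, adjusted p = 0.0197), lost with an estimated correlation (adjusted p = 0.486), with fry (0.0916) and without replicate 1 (0.0538), 2 (0.0614) or 3 (0.274). NGA3 was at 6.38 ± 0.56 against 3.34 ± 0.87 CPM.

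Smaller shifts of whole lists in this step held few or no called members. The transition list was down, 3 of 20 (camera, adjusted p = 0.0438), lost with an estimated correlation (adjusted p = 0.497), with fry (0.114), with library totals (0.0932) and without replicate 1 (0.0836) or 3 (0.23). Cell division genes were down (camera, adjusted p = 0.0085), lost with an estimated correlation (adjusted p = 0.654), with fry (0.213) and without replicate 2 (0.0728) or 4 (0.0729), CYCB1;3 being at 29.3 ± 2.0 against 33.9 ± 1.8 CPM. DNA replication genes were down (camera, adjusted p = 0.0125), lost with an estimated correlation (adjusted p = 0.774), with fry (0.322) and without replicate 1 (0.116) or 4 (0.161), PCNA1 being at 42.5 ± 5.4 against 53.2 ± 14 CPM. Vascular genes were down (camera, adjusted p = 0.00575), lost with an estimated correlation (adjusted p = 0.566), with fry (0.186) and without replicate 2 (0.0648) or 3 (0.188), IRX1 being at 5.72 ± 1.2 against 6.97 ± 0.28 CPM.

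The step from day 3 to day 4 held 190 rises and 96 falls (edgeR, adjusted p under 0.05), with 8 rises beyond a fold of 1.5 (glmTreat). Rises went to 78 and 84 without day 3 replicates 1 and 2, to 102, 105 and 96 without day 4 replicates 1, 2 and 4, and to 288 without day 5 replicate 1. Falls went to 33 and 52 without day 3 replicates 1 and 2, to 39, 58 and 45 without day 4 replicates 1, 2 and 4, and to 148 without day 5 replicate 1. DRNL (7.69 ± 2.1 to 3.49 ± 0.86 CPM), an organ founder gene, and AIL6 lost their calls without day 3 replicate 1 (adjusted p = 0.0536 each), and KNAT6 (-0.33) without day 3 replicate 1 or 2 (0.068). SAP (-0.59) lost its call without day 3 replicate 1 or day 4 replicate 1 or 4 (0.117), FLS6 without day 3 replicate 1 or 4 or day 4 replicate 1 (0.0757), and NGA3 without day 3 replicate 2 or 3 or day 4 replicate 1 (0.0693). LFY (-0.38), SEP2 (0.41), AGL24 (-0.27), WUS, CUC1, RXF26, UGT74F2, NAP, CORI3 and CYP86A4 lost theirs without any of 4 to 16 libraries (up to 0.187).

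The last step, day 5 against day 4, brought rises in cuticle and jasmonate genes (n = 4 per day). RXF26 (AT1G58430) rose from 4.56 ± 2.1 to 36.5 ± 18 CPM (log2 change 3.00, SE 0.37, adjusted p = 6.14e-05). CYP86A4 (AT1G01600), which makes cutin monomers, rose from 4.91 ± 2.1 to 31.3 ± 9.3 CPM, the cutin gene GPAT6 from 10.2 ± 3.0 to 37.0 ± 12 and SHN1 from 9.35 ± 2.6 to 39.1 ± 15. Of 15 cuticle genes 11 rose (camera, adjusted p = 3.02e-08, and adjusted p = 0.184 with an estimated correlation). AOC2 rose from 15 ± 11 to 79.3 ± 15 CPM, AOC1 from 4.63 ± 3.0 to 24.8 ± 11, LOX3 from 24.3 ± 8.5 to 97.6 ± 31 and OPR3 from 84.4 ± 18 to 163 ± 41. Of 11 jasmonate genes 9 rose, all 11 adjusted over the list alone (camera, adjusted p = 1.30e-09, and adjusted p = 0.139 with an estimated correlation). TAT3 (AT2G24850), a jasmonate-responsive aminotransferase gene, rose from 4.08 ± 3.0 to 20.5 ± 7.8 CPM, FAMT (AT3G44860), a methyltransferase gene, from 6.91 ± 3.7 to 37.0 ± 35 and the cold-regulated COR15A (AT2G42540) from 8.64 ± 4.2 to 42.7 ± 16. The handling list moved in the same step, 4 of 8 (camera, adjusted p = 0.00843), lost with an estimated correlation (adjusted p = 0.255) and without replicate 3 (0.0521). TCH4, a touch gene, was at 102 ± 60 against 35.4 ± 23 CPM.

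Falling in the last step were PUP4 (AT1G30840), a purine permease gene (13.6 ± 1.4 to 7.92 ± 0.87 CPM), FTM1 (AT1G43800), tied to the floral transition (47.9 ± 15 to 16.0 ± 7.0), and DRNL (3.49 ± 0.86 to 1.67 ± 0.50). CHR42 (AT5G20420, 18.7 ± 4.1 to 10 ± 2.9) and CYP709B2 (AT2G46950, 12.9 ± 2.3 to 7.42 ± 0.77) fell as well. CLV3 fell from 0.390 ± 0.063 to 0.142 ± 0.084 CPM, STM by 0.37, LAS, of axillary meristems, by 0.50, UFO from 28.6 ± 4.7 to 18.4 ± 0.58 and CAL by 0.57. Of 15 meristem and boundary genes 7 fell (camera, adjusted p = 3.14e-05, and adjusted p = 0.184 with an estimated correlation). SVP fell by 0.38, AGL24 by 0.32 and AGL71 by 0.47, with SPL5 at 142 ± 33 against 92.0 ± 9.9 CPM, and the transition list was not called (2 rises and 5 falls of 20, adjusted p = 0.677). Organ identity genes were not called either (adjusted p = 0.938), nor polarity genes (2 rises and 3 falls of 15, adjusted p = 0.123), where KAN3 and AS2 rose by 0.64 each and ETT fell by 0.32. CYCD3;1, which drives entry into the cell cycle, fell from 166 ± 6.2 to 130 ± 14 CPM.

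Cell division genes fell as a list, 2 of 15 (camera, adjusted p = 0.000978, and adjusted p = 0.498 with an estimated correlation), with CYCB1;1 at 60.0 ± 4.3 against 69.5 ± 4.7 CPM. YUC1 fell by 0.50, and the auxin list was down, 1 of 12 (camera, adjusted p = 0.0465), lost with an estimated correlation (adjusted p = 0.279), with library totals (0.0722) and without replicate 2 (0.14) or 3 (0.112). The flavonoid list was up, 1 of 10 (camera, adjusted p = 0.0169), lost with an estimated correlation (adjusted p = 0.775), with fry (0.163) and without replicate 2 (0.0916). This step held 1531 rises and 872 falls (edgeR, adjusted p under 0.05), 65 and 1 of them beyond a fold of 1.5 (glmTreat), and with library totals 44.2% of its calls were rises, against 63.7%. Rises went to 650 and 969 without day 4 replicates 1 and 3, and falls to 298, 555 and 497 without day 4 replicates 1 and 3 and day 5 replicate 4. Without day 4 replicate 1 the calls of NAC044 (60.4 ± 35 to 20 ± 7.1 CPM, adjusted p = 0.051), CRF6 (0.0903), NAC13 (0.0791), HSFA2 (0.0603) and CYCB1;1 (0.0751) ended. CYCB1;1 also ended without day 4 replicate 3 or day 5 replicate 4, LTI78 (38.8 ± 28 to 177 ± 59 CPM) without day 4 replicate 1 or 3 (0.0679), and SPL5 without day 5 replicate 4 (0.0509). The calls of SEP3 (0.41) ended without day 4 replicate 1, 2 or 3 (0.0702), of TCH4 without those or day 5 replicate 3 (0.102), and of LFY (-0.32), FUL and TT7 without any of 6 to 15 libraries (up to 0.15).

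**Figure D4:**
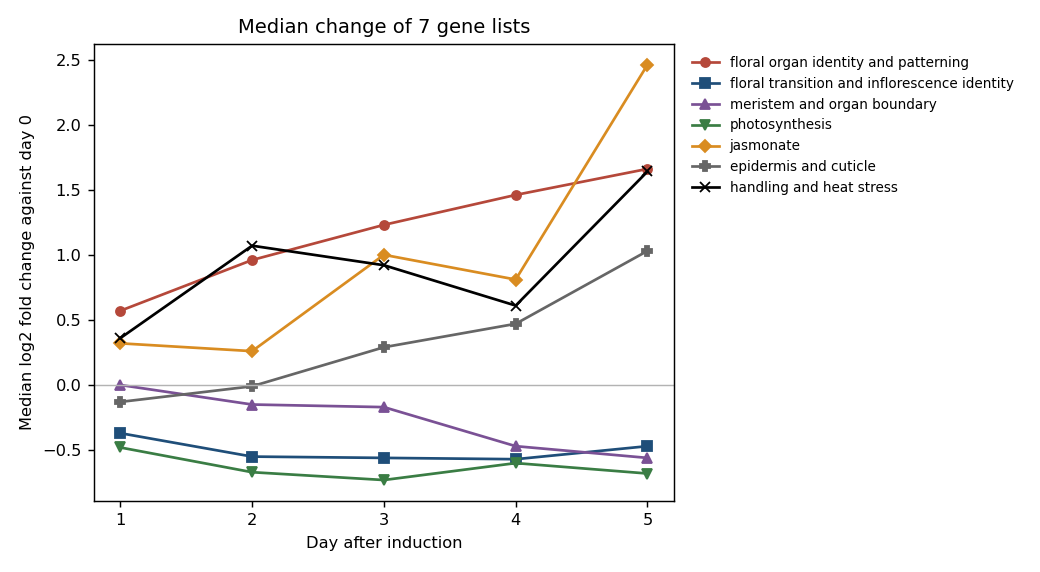
Median log2 fold change against day 0 on the vertical axis for the members of 7 gene lists, by day after induction, with no error shown. Photosynthesis genes lie below day 0 on every day, with a median of -0.48 at day 1.

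Tapetum genes varied widely between libraries of a day. The summed level of 14 tapetum genes (AMS, MS1, TDF1, A9, ATA7 and others) was 1.27 ± 0.74 CPM at day 0, 14.0 ± 20, 15.8 ± 21, 28.1 ± 52 and 5.18 ± 3.1 at days 1 to 4 and 19.9 ± 24 at day 5 (n = 4). The highest were day 1 replicate 3 (43.3), day 2 replicate 4 (46.2), day 3 replicate 4 (106) and day 5 replicate 4 (54.9 CPM). Other libraries also lay above the day 0 range of 0.386 to 2.2 CPM. Among them were day 1 replicate 4 (10), day 2 replicate 3 (11.3), day 5 replicate 2 (17.1) and day 4 replicates 1, 2 and 4 (6.16 to 7.22 CPM). The 14 genes were chosen by a rule in a script after the values per library were seen. Samples high in them stayed in every comparison.

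**Figure D5:**
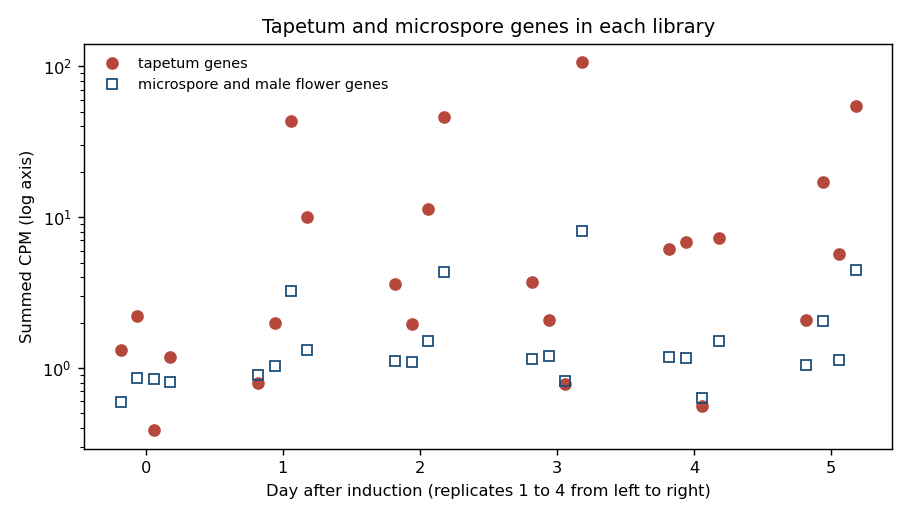
Summed CPM on a log axis for 14 tapetum genes (red circles) and 6 microspore and male flower genes (blue open squares) in each of 24 samples, by day after induction with replicates 1 to 4 from left to right. Both sets are highest in day 3 replicate 4, where the tapetum genes reach 106 CPM.

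Over the 198 list comparisons 67 were called with the preset correlation, 39 up and 28 down, 7 of them also with an estimated correlation, and fry called 70. The 7 were the organ identity list at days 1 to 4 against day 0 and at day 2 against day 1, and the meristem and auxin lists at day 4 against day 3. Leaving out the 4 libraries of highest tapetum level together, a setting chosen after the values were seen, ended 9 of the 67 calls. These were the anther and tapetum list at day 1 (adjusted p = 0.0559) and day 3 (0.177) and the polarity list at day 2 (0.0506) against day 0. At day 2 against day 1 they were polarity (0.0916), cuticle (0.305) and photosynthesis (0.0553), at day 3 against day 2 photosynthesis (0.248), and at day 4 against day 3 transition (0.06) and DNA replication (0.228).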

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

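The tests on tapetum levels within days, on the hour of sampling for AOX1A and its companions, and on drenching were chosen after the results were seen. In 13 of 198 groups of 4 samples, 1 sample lay far from the other 3, where chance gives about 1 in 20, or 9.9 groups. Most of the 13 concern a few libraries.

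Day 3 replicate 4 stood apart in 4 values: CAL at 8.74 CPM (others 12.2 to 12.8), CRC at 26.3 (8.22 to 11.2), SVP at 26.4 (33.6 to 34) and the summed tapetum genes at 106 (0.78 to 3.69). Day 0 replicate 3 stood apart in NDB4 at 0.425 CPM (0.184 to 0.224), ERF71 at 2.28 (0.374 to 0.59) and UGT73B4 at 0.463 (0.0748 to 0.111). Other samples far from the rest of their day were day 4 replicate 2 in AP3 (186 CPM, others 165 to 168), day 5 replicate 1 in STM (52.9, others 73.2 to 77.3) and day 2 replicate 4 in SPL/NZZ (1.45, others 0.323 to 0.422). So were day 4 replicate 3 in the tapetum genes (0.557, others 6.16 to 7.22) and day 5 replicate 3 in NDB4 (14.3, others 4.18 to 5.75). Day 3 replicate 3 had the largest total of its day, 28 M counts (others 26.8 to 26.9).

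On each of days 1, 2, 3 and 5 tapetum genes were much higher in a single library than in the rest of that day. A candidate explanation is that these samples held some older flowers or anthers. A separate set of 6 microspore and male flower genes followed the 14 tapetum genes across the 24 samples (day-centred log2 levels, Pearson r = 0.924, Spearman rho = 0.898, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 1e-05). Without the 2 farthest libraries r was 0.879, and it was 0.78 in batch 1 and 0.92 in batch 2. Reads carried over in 1 batch are argued against by the runs, whose levels differed at most 1.05-fold in the highest libraries. Carry-over before the runs stays open. Tapetum formed evenly as the days pass is argued against as the source of the high levels at days 1 to 3. Those libraries reached 43.3, 46.2 and 106 CPM, against 0.557 to 7.22 in the 4 samples of day 4. For the high library of day 5, and for tapetum formed unevenly between samples, older flowers cannot be told apart. The share of variance within days over days 1 to 5, 0.938 (permutation p = 0.901), does not decide this, since it only restates the pattern.

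AOX1A, NDB4, ERF71, DTX1 and UGT73B4 were higher on every day after induction than at day 0, AOX1A at 10.5 ± 4.5 CPM (n = 4) at day 0, 257 ± 64 at day 2 and 124 ± 50 at day 5. Low oxygen that still held at the day 1 sampling is argued against by a separate set of 22 hypoxia genes. Their median log2 change at day 1 was -0.13 (95% bootstrap interval over genes -0.4 to -0.01), with 2 falls, 3 adjusted over the list alone. A spell of low oxygen after drenching that ended before that sampling cannot be judged from these values and stays open. A different hour of sampling at day 0 cannot be told apart either, since it does not forbid the further change from day 1 to day 2, at least 1.25 in log2 for each of the 5 genes (NDB4, 1.28, adjusted p = 0.265, did not pass the test). Drenching and handling without AP1 activity may explain the rise and cannot be told apart from an effect of AP1, since 0 samples were drenched without active AP1.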

How the results depend on the processing

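The settings without 4 libraries of high tapetum level and with day 1 as the reference were chosen after the results were seen. With the replicate number as a replicate block, 9470 genes changed over the days (9219 shared with the 9661 of the fit without it). Each other count stayed within 1.5 times and 67 list comparisons were called. Over all tested genes, pairing by number was weak on average. Deviations from the day means correlated at 0.0434 on average for 60 pairs with the same number (-0.312 to 0.604, 17 of them above 0.1). For 180 pairs with other numbers the mean was -0.0148 (-0.504 to 0.508). Of 24 samples 10 were closest to a sample with their own number, though fewer pairs share a number than not. In the summed tapetum genes replicate 4 was the highest sample on days 2 to 5 (46.2, 106, 7.22 and 54.9 CPM). Replicate 2 was the highest at day 0 (2.2 CPM) and replicate 3 at day 1 (43.3 CPM). An effect shared by samples of the same number is therefore not excluded. Of 623 calls of named genes, 623 were kept with DESeq2, 615 with the block, 606 with library totals, 425 without replicate 2 and 254 against a fold of 1.5, with no direction reversed. Alternatives for normalized values do not apply, since counts were deposited. In each pair below rises come before falls, and the cause was not tested unless the setting tests fewer genes or samples.

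A mean of at least 10 CPM tests fewer genes and gave 6384 over days, 1885 rises at day 3 and 2274 and 2883 falls at days 4 and 5 against day 0. It gave 148 and 44 for day 2 against day 1, 48 and 15 for day 3 against day 2 and 114 rises for day 4 against day 3. Library totals gave 1441 rises at day 1 against day 0, 125 falls for day 2 against day 1 and 1618 for day 5 against day 4. DESeq2 gave 443 and 146, 254 and 77, and 324 and 159 for the steps to days 2, 3 and 4. Batch 1 alone, with fewer counts, gave 193 and 47, 75 and 15, 118 and 46, and 988 and 404 for the steps to days 2 to 5. Batch as a covariate on the runs gave 1278 rises at day 1 against day 0, and 480 and 201, 257 and 90, and 438 and 195 for the steps to days 2 to 4. The 2 compared days alone gave 470 and 125, 17 and 4, 113 and 34, and 492 and 260 for the steps to days 2 to 5. Without the 4 libraries the steps to days 2 and 3 gave 181 and 32, and 35 and 7, and day 5 against day 4 gave 436 falls. Day 1 as reference gave 1189 and 749 at day 3 and 2242 and 1633 at day 4. An estimated correlation called 7 list comparisons. Without the 4 libraries 58 of the 67 list comparisons were still called.

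Against a fold of 1.5 (glmTreat) days 1 to 5 against day 0 gave 64 and 22, 444 and 185, 700 and 404, 1014 and 535, and 1778 and 633. The steps to days 2 to 5 gave 27 and 0, 1 and 0, 8 and 0, and 65 and 1. At unadjusted p under 0.05 edgeR's glmTreat gave 49, 44 and 80 falls for the 3 steps with 0, and DESeq2 called 146, 77 and 159 falls there with no fold threshold. Neither set of counts is evidence of falls beyond a fold of 1.5. Among 19747 genes many can pass an unadjusted p by chance, and the DESeq2 test asked for no fold.

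With a replicate or a library left out, 6336 to 10203 genes changed over days. Rises and falls against day 0 ranged over 175 to 1072 and 162 to 1446 at day 1, 1310 to 2612 and 1326 to 2757 at day 2, 1995 to 3239 and 1906 to 3115 at day 3, 2514 to 3840 and 2230 to 3722 at day 4, and 3881 to 4909 and 3443 to 4767 at day 5. For the steps they ranged over 76 to 492 and 6 to 137 to day 2, 4 to 198 and 1 to 54 to day 3, 24 to 288 and 12 to 148 to day 4, and 646 to 1773 and 218 to 1048 to day 5. Called list comparisons, run only with a whole replicate left out, ranged over 59 to 66. The lowest counts came without replicate 2 of every day, except day 5 against day 0 and the lists (without replicate 3).

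In other splits of the samples into groups of the same sizes, none called as many genes as the real groups for all results but 1, though 1 of 35 is the smallest share that 8 samples can give. The other splits mix the days, so a difference between days widens the spread within their groups and lowers their counts. Those low counts are therefore no estimate of the false calls among the real ones. Over days, 1 of 100 splits called as many as the real 9661 genes (highest other 18). Against day 0, 1 of 35 splits of the 8 samples did so at each day: day 1 with 2234 (highest other 1), day 2 with 3919 (1), day 3 with 4922 (0), day 4 with 6097 (0) and day 5 with 7109 (0). The same held for the steps to day 2 with 595 (0), day 4 with 147 (2) and day 5 with 752 (243, exchanging day 4 replicate 4 with day 5 replicate 1). For day 3 against day 2 chance is not excluded: 2 of 35 splits called as many as the real 21, the other calling 44 when day 2 replicate 3 is exchanged with day 3 replicate 1.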

Other observations

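The morning and evening gene tests and the hypoxia set were written before their values were seen, and the day 5 replicate 1 values below were looked at after its place in the principal components was seen. Between day 1 and day 5, genes that peak in the morning were mixed: COL1 rose by 1.85 (SE 0.14, adjusted p = 7.5e-10, n = 4 per day), and LNK4 by 1.62 (adjusted p = 0.000465). CDF3 rose by 0.95 (adjusted p = 0.00179) and LNK3 by 1.03 (adjusted p = 0.0319), while RVE4 fell by 0.32 (adjusted p = 0.0367). That made 4 rises and 1 fall among 13 genes, with a median log2 change of 0.12. Among 5 evening genes COR28 fell by 0.67 (adjusted p = 0.0349 over all genes, not called when adjusted over the list alone). Their median was -0.2.

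ASN1, an asparagine synthetase gene induced by low sugar, was at 196 CPM in day 5 replicate 1, against 39, 21.3 and 95.3 in the other samples of day 5. It was at 43.2 CPM in day 0 replicate 3, against 5.24, 14.4 and 7.37. AOX1A was at 52.6 CPM in day 5 replicate 1, against 133, 170 and 142 in the other samples of day 5. LOX3 was at 143 CPM in that library, against 77.3 to 84.8 in the other samples of day 5. The chi-square per degree of freedom of day 5 replicate 1 against the other replicates of its day was 65 to 66.1. Among those other replicates it was 4.36 to 13.1. In the split of days 2 and 3 that called 44 genes, AOX1A was at 188, 130, 173 and 119 CPM in day 2 replicate 3 and day 3 replicates 2 to 4, and at 277, 336, 226 and 278 CPM in the other 4 samples.

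Of the fixed clock list 4 of 17 genes fell at day 1 against day 0 (4 rises and 4 falls adjusted over the list alone). The list was not called against day 0 on any day (camera, adjusted p = 0.523 to 0.96). It mixes morning and evening genes, whose opposite changes cancel in camera's test of a shared direction. The missing call therefore decides nothing about the hour of sampling. A candidate explanation for the genes that differed is a later hour of sampling at day 0. In separate sets of genes, the morning genes exceeded the evening genes by 0.88 in mean log2 change at day 1 against day 0, more than in nearly all of 8568 ways to divide the 18 genes (exact one-sided permutation p = 0.000233). That p treats genes as independent, though they can change together, and does not measure the spread between samples. A change that goes on with development cannot be told apart from a later hour of sampling. The same difference between day 1 and day 5 was 0.68, smaller than the step at day 1 in 88.2% of resamples of the genes. The labels give the hours of induction (8 h after lights on at first, 4 h on later days) but not the hour of sampling. A different hour at day 0, if there was one, would bear on every comparison against day 0, not on clock genes alone. Its part in the falls of COR27, JMJD5 and the photosynthesis list was not tested.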
